A study of Homo sapiens with 6 samples.

How the data were processed

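Total RNA of 6 HT29 cultures, 3 with cocoa extract and 3 controls, grown in F12 medium with 7% serum on 100 mm plates, was purified with spin columns, per the labels' protocols. It was labelled with biotin on an automated system and hybridised to Affymetrix Human Genome U133 Plus 2.0 arrays, 1 array per culture. The expression values were made by the authors with RMA (robust multi-array average, which corrects background, normalises by quantiles and summarises probes), per the submitters' processing notes, and the series text names the GeneSpring GX software. The versions of both, the annotation used and any filter are not given in the sources used here. The deposited log2 table holds 54675 probe sets for the 6 arrays. Its values run from −2.42 to 4.02, and each probe set has a median of 0 over the arrays (largest absolute median 5.0e-07), so that the authors' table had been centred per probe set. That the scale is log2 follows from RMA, since the table itself does not name its base. Because of the centring, signal over background and detection are unknown, probe sets cannot be ranked by level, and compression of small differences near background cannot be judged. The medians of the 6 columns were between −0.0132 and 0.0073. Scanner files, scan dates and hybridisation batches were not analysed here.

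Probe sets were named through the platform annotation. Of 54613 probe sets without the 62 Affymetrix control probe sets, 41091 carried 1 gene symbol, 1801 several and 11721 none. By gene identifier 41037 of the 41091 matched the RefSeq gene table used here, and 0 symbols needed an update. Genes were named only from probe sets with 1 symbol. A gene's value was the mean of its probe sets, the rule set for a table without levels in place of the brightest probe set, which gave 19775 genes, 9252 with 1 probe set and 10523 with several. Of 1442 changed genes with several probe sets, 1252 had the same sign in all of them, and 6 changed genes had a probe set called in the opposite direction. The 13522 probe sets without a single symbol stayed in the count of probe sets, where 524 of them changed, and out of all others.

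The comparison was cocoa minus control on log2 values over all 6 arrays with limma 3.58.1 (lmFit and eBayes, no trend and no robust prior) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 difference is a difference of group means, its SE is the moderated standard error, and a fold is 2 to the power of the difference. The design, the alternatives, 32 gene lists and the rule for named genes were fixed before the data were examined. The lists held 487 entries for 475 genes, of which 438 entries and 428 genes were tested. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 32 lists; the alternatives were an estimated correlation and fry, which tests whether a set's genes move one way on balance without comparing them with other genes. Genes were named by a rule: the 10 largest increases and 10 largest decreases among changed genes whose groups did not overlap, up to 4 changed members of each list by size, and a fixed set of well known response genes. The rule named 106 genes, of which 101 were past the threshold, 43 of these with several probe sets and 0 with a probe set called in the opposite direction. IFIT2, IRF7, IRF9, CDC20, HSPB1 and SLC39A10 were added after their values were seen. Some genes named by the rule are not described singly below.

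Replicates were compared before averaging. The SD of the difference between 2 arrays was 0.175 to 0.215 among controls, 0.22 to 0.264 among cocoa arrays and 0.269 to 0.333 across groups, and no 2 arrays were copies of each other. Alternatives were the replicate number as a block, a robust variance prior, array weights, quantile normalisation, centring of each array on its median, removal of probe sets with the suffixes _s_at and _x_at, other fold thresholds, and leaving out each array in turn. Covariates from the 18S ribosomal RNA control probe sets and from the 5′ minus 3′ control probe sets of actin and GAPDH, and the median of a gene's probe sets, were added after the data were seen. A filter on dim probe sets and an intensity trend were not run because the table holds no levels.

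The steps were tested on simulated data with the spread of these arrays, in which 50 of 19775 genes were changed at each of 4 sizes. At a log2 change of 0.5, 70% were recovered, at 1, 96%, and at 2 and at 3, 100%. Of 193 genes called, 10 were unchanged ones. In the same simulation 2 of 2 shifted lists and 0 of the other 30 were called. The simulated genes were drawn independently of each other, so this does not test false calls of lists whose genes are correlated. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.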

Results

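Gene expression was measured in HT29 cells, an established human line derived from a colorectal adenocarcinoma. A total of 300000 cells were plated, and on the next day 3 cultures received a polyphenolic extract of cocoa (500 µg, with no volume given) and 3 served as controls. RNA was taken after 24 h and each culture was read on its own oligonucleotide array, so that the comparison rests on 6 arrays, 3 per group. The controls are titled untreated in the sample names, while the protocol states that they received saline. The question of the study was which transcripts changed within a day of exposure to the extract. The deposited values are log2 expression centred for each probe set on the median of the 6 arrays, and they therefore give differences between arrays and no expression levels. The number of arrays limits the precision. Whether the 3 cultures of a group were grown on separate days is not given in the sources used here, so the p-values measure only the spread between these cultures.

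The strongest response to the cocoa extract was an increase of genes of the interferon response. TRIM22, an antiviral ubiquitin ligase, rose 15.5-fold (log2 difference 3.95, SE 0.16, n = 3 arrays per group), and IFI44L, a gene induced by type I interferon, rose 14.1-fold (3.81, SE 0.17). IFIT1, which binds viral RNA lacking host-type caps, rose by 2.52 on the log2 scale (SE 0.13). EPSTI1, an interferon-inducible gene of macrophages and epithelia, rose by 2.36 (SE 0.087), and IFITM1, a membrane protein that restricts virus entry, by 2.36 (SE 0.18). The other 5 of the 10 largest increases were SLC2A10, a facilitative glucose transporter (2.33, SE 0.10), DDX60, an RNA helicase of antiviral signalling (2.29, SE 0.13), GIMAP2, a GTPase of the immunity-associated family (2.28, SE 0.16), LAMP3, a lysosomal membrane protein (2.28, SE 0.16), and MX2, a dynamin-like antiviral GTPase (2.27, SE 0.20).

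The largest decrease was that of TFF1, a secreted trefoil peptide that protects the mucosa, which was 6.83-fold lower with cocoa (log2 difference −2.77, SE 0.085, n = 3 arrays per group). DKK1, a secreted inhibitor of Wnt signalling, fell by 1.92 on the log2 scale (SE 0.083), and the long non-coding RNA LINC00973 fell by 1.79 (SE 0.18). REG4, a secreted lectin-like protein of the intestinal epithelium, fell by 1.58 (SE 0.13), and CAV1, the main protein of caveolae, fell by 1.42 (SE 0.069). GPAT3, an acyltransferase of triglyceride synthesis, fell by 1.33 (SE 0.080), and S100A2, a calcium-binding protein, fell by 1.29 (SE 0.11). SPINK4, a peptide of goblet cells, FOSL1, a subunit of the AP-1 transcription factor, and ARL14, a small GTPase, each fell by 1.06 (SE 0.087, 0.086 and 0.088). The limma adjusted p (Benjamini-Hochberg) of these 20 genes, taken from those whose groups did not overlap, was between 1.49e-06 and 0.000431. All 20 calls were kept in each of the 6 fits that left out 1 array. TRIM22, IFITM1, SLC2A10, DDX60 and GPAT3 each rest on 1 probe set with the suffix _s_at, which marks possible matches to several transcripts. The fit without such probe sets does not measure them.

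**Figure D1:**
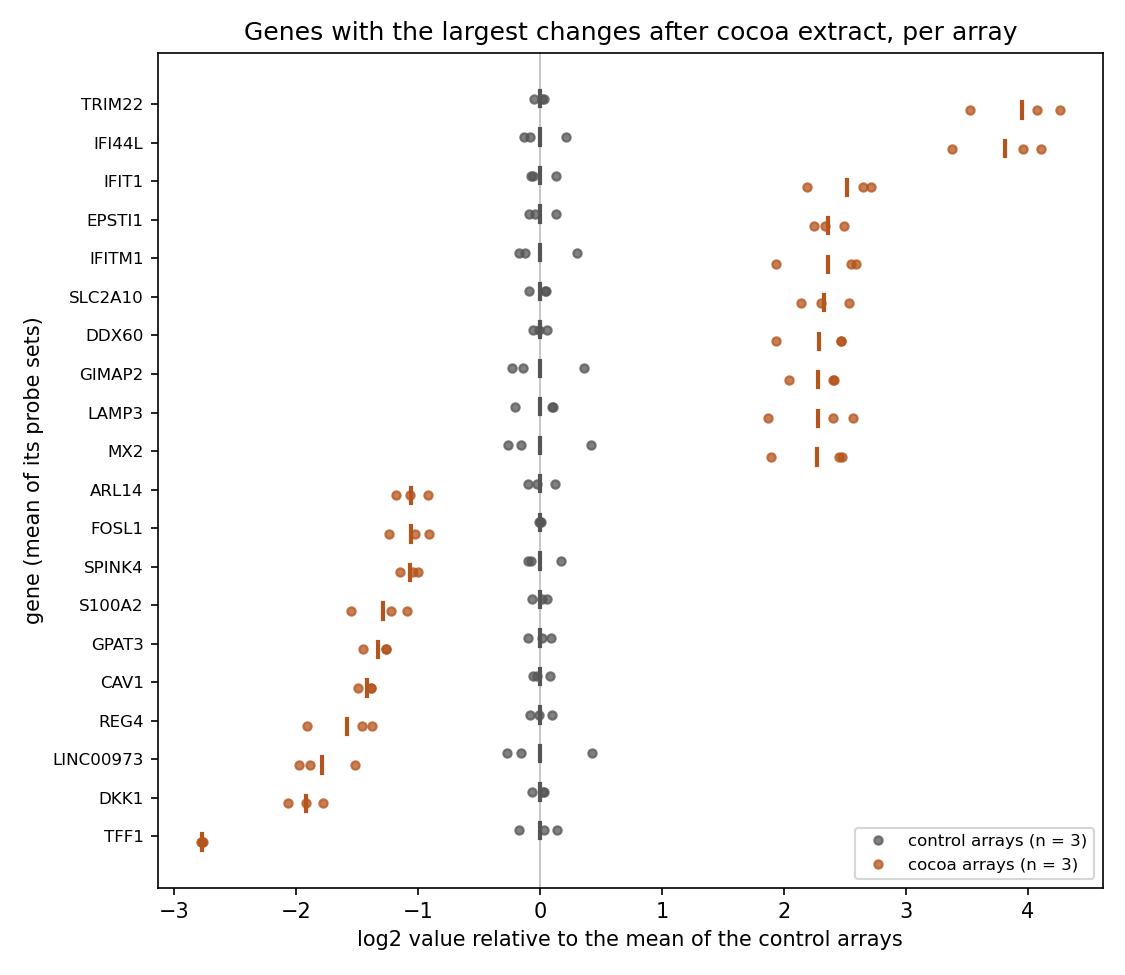
Log2 value of each array relative to the mean of the 3 control arrays (horizontal axis) for the 10 genes with the largest increase and the 10 with the largest decrease (vertical axis); points are single arrays, grey for control and brown for cocoa (n = 3 each), and vertical bars are group means. The genes were taken from those whose groups did not overlap, and the mean differences run from 3.95 for TRIM22 to −2.77 for TFF1.

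Of 19775 genes, 2666 (13.5%) changed at a Benjamini-Hochberg adjusted p below 0.05 in limma, 1456 of them higher and 1210 lower with cocoa. Large changes went mostly upward: of 446 genes that changed at least 1.5-fold, 365 were higher and 81 lower, and of 107 that changed at least 2-fold, 97 were higher and 10 lower. On the level of probe sets, 4358 of 54613 changed, 2555 of them higher and 1803 lower. The cocoa and control arrays did not overlap in 6417 genes, which is 32.5% of those tested against 10% given by chance. The first principal component held 59.7% of the variance between arrays and separated the groups, with control arrays between −17.28 and −15.74 and cocoa arrays between 12.63 and 20.07. The number of changed genes depended on single arrays and fell to 1315 without control array 2 (851 higher and 464 lower) and to 1623 without control array 1. Without control array 2, 1416 probe sets changed. With the 18S ribosomal RNA signal of each array as a covariate, 1103 genes changed (787 higher and 316 lower). With the 5′ to 3′ signal of actin and GAPDH as a covariate, 1411 changed (919 higher and 492 lower). Both signals stood apart in cocoa arrays 2 and 3. With either covariate 395 genes changed at least 1.5-fold. Of 101 changed genes chosen by the naming rule, 64 kept their call with the first covariate and 67 with the second, and all 101 kept their sign.

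Of 32 gene lists fixed in advance, 8 shifted in limma's camera test with a preset correlation of 0.01, 3 upward and 5 downward. None of the 8 calls held with a correlation estimated from the 6 arrays, and the p of that test is given with each list. On 6 arrays that test has little power. The interferon list, with all 16 measured members higher, had an unadjusted camera p of 0.0138 in it, so not passing does not decide against a list. A regrouping of the same arrays that mixed cocoa and control gave 9 calls at the preset correlation. Its groups held unequal numbers of cocoa arrays, so part of the cocoa difference remained. It therefore does not show how many calls arise without an effect. The preset 0.01 lay below the estimated correlation of every called list except metallothioneins (−0.036). In the others it ran from 0.109 for goblet cell genes to 0.43 for the interferon response, with 0.279 for DNA replication. Where genes of a list are correlated, calls of lists with small shifts carry less weight than their p-values state.

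All 16 measured members of the interferon response list rose, with a median log2 difference of 1.204 (camera adjusted p = 5.86e-25; adjusted p = 0.221 with an estimated correlation). The count was also 16 when adjusted over the list alone. Besides IFI44L and IFIT1, the list held MX1, a GTPase that blocks virus replication (2.18, SE 0.097), and OAS2, an enzyme that makes 2′-5′ oligoadenylates from double-stranded RNA (2.05, SE 0.12). The transcription factors IRF9 (1.21, SE 0.097) and IRF7 (0.92, SE 0.11), both of interferon signalling, rose as well. Of the 16, 15 kept their call in every fit without 1 array. The exception was IFIT2, whose adjusted p was 0.0689 without control array 2 and 0.0133 to 0.0689 over the fits without 1 array. The list mean was between 0.62 and 0.89 in the 3 cocoa arrays and between −0.79 and −0.60 in the controls. With the 18S signal as a covariate 15 of the 16 members stayed past the threshold.

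**Figure D2:**
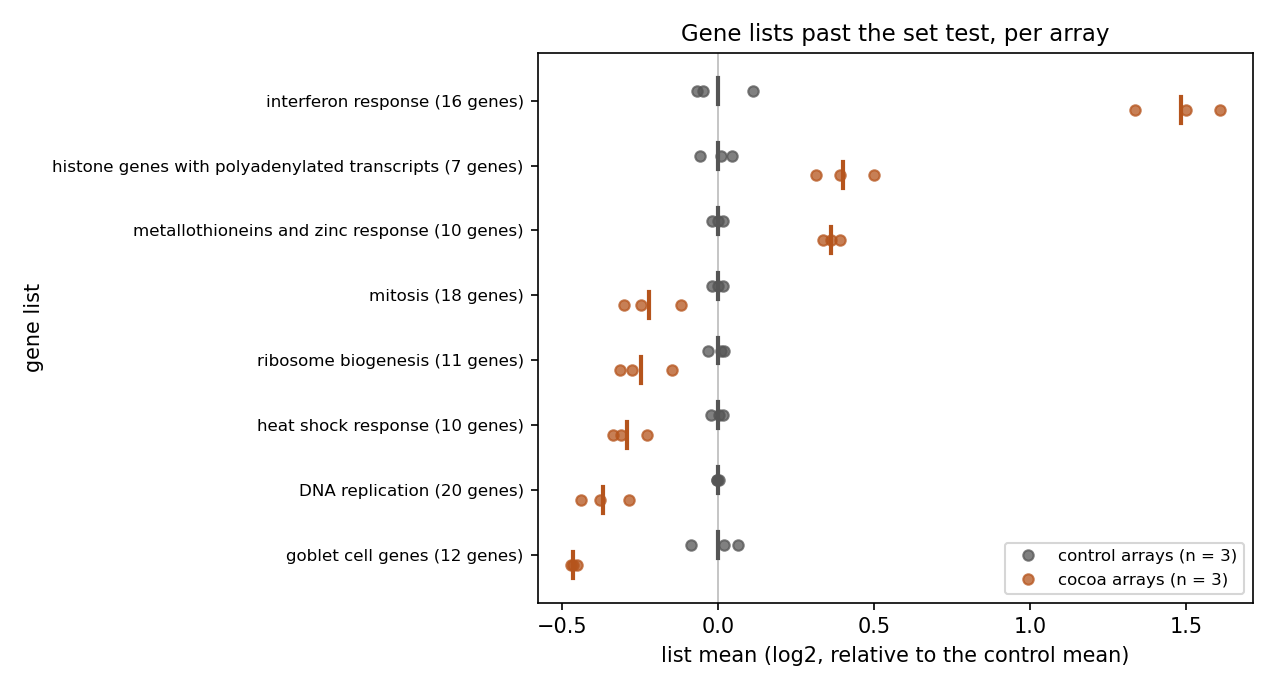
Mean log2 value over the genes of each list, relative to the mean of the control arrays (horizontal axis), for the 8 lists past the camera test (vertical axis, with the number of measured genes); points are single arrays, grey for control and brown for cocoa (n = 3 each), and bars are group means. The interferon response list stands at 1.48 in the cocoa group, and the other 7 lists differ by less than 0.5 in either direction.

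DNA replication genes were lower with cocoa. Of 20 measured, 14 fell, none rose and 6 did not pass, and 18 were lower when adjusted over the list alone; the median log2 difference was −0.35 (camera adjusted p = 2.34e-11; adjusted p = 0.369 with an estimated correlation). CDC6, which loads the replicative helicase (−0.66, SE 0.11), POLA1, the catalytic subunit of the polymerase that starts new strands (−0.60, SE 0.085), CDC45, a part of the active helicase (−0.56, SE 0.083), and MCM5, a subunit of the helicase ring (−0.53, SE 0.094), had the largest decreases. Of the 14, 9 kept their call in every fit without 1 array, and 6 kept it with the 18S covariate. The list mean was −0.12 in cocoa array 1, −0.27 in cocoa array 2 and −0.21 in cocoa array 3, against 0.16 to 0.17 in the controls. The 18S signal was −0.51 in cocoa array 1, 3.31 in cocoa array 2 and 1.40 in cocoa array 3, and −1.12 to 0.51 in the controls.

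**Figure D3:**
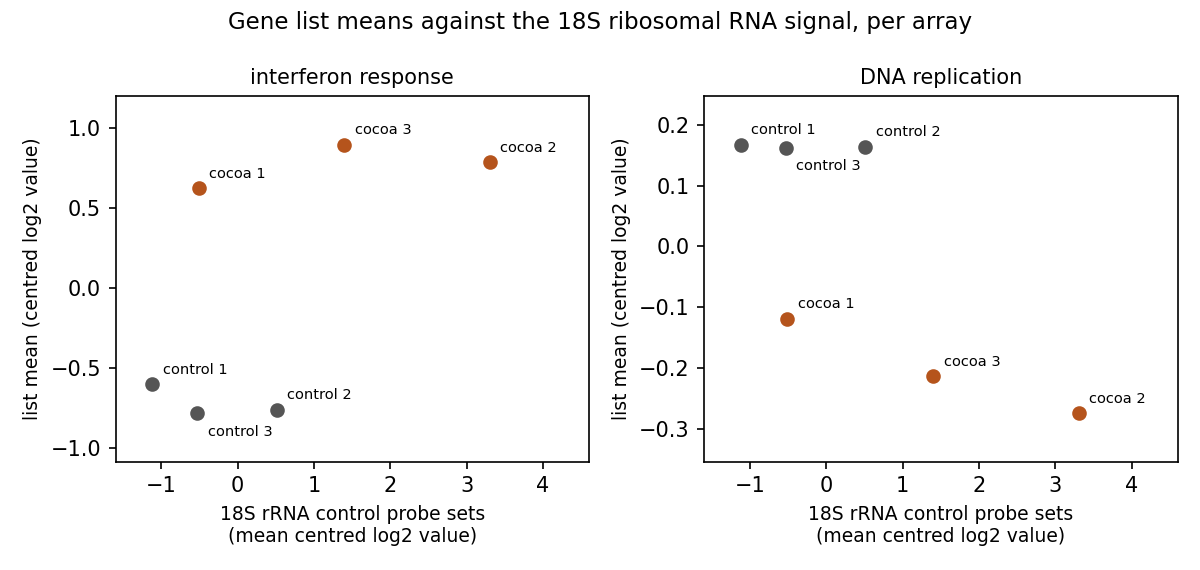
Mean centred log2 value of the interferon response list (left) and of the DNA replication list (right) on the vertical axis against the mean centred log2 value of the 18S ribosomal RNA control probe sets (horizontal axis); each point is 1 array, grey for control and brown for cocoa. Cocoa arrays 2 and 3 stand at 3.31 and 1.40 on the horizontal axis, and cocoa array 1, at −0.51, lies among the controls there and apart from them on the vertical axis.

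In the mitosis list 7 of 18 genes fell, none rose and 11 did not pass (8 lower when adjusted over the list alone; median −0.18; camera adjusted p = 0.00021; adjusted p = 0.446 with an estimated correlation). CCNF, the F-box protein cyclin F, fell by 0.59 on the log2 scale (SE 0.082), PLK1, a kinase of mitotic entry, fell by 0.49 (SE 0.085), and CDC20, an activator of the anaphase-promoting complex, fell by 0.39 (SE 0.075). These 3 kept their call in every fit without 1 array. AURKB (−0.47, SE 0.12) and CCNA2 (−0.43, SE 0.085) fell more than CDC20 but held less well. The call of AURKB was kept in 2 of the fits without 1 array (adjusted p 0.00766 to 0.103). That of CCNA2 was lost without control array 2 (0.00413 to 0.0532 in the fits without 1 array). With the 18S covariate 1 of the 7 members, CCNF, kept its call. The list mean was −0.02 in cocoa array 1, −0.15 in cocoa array 2 and −0.20 in cocoa array 3, against 0.08 to 0.11 in the controls. The proliferation marker MKI67 had a log2 difference of −0.14 (SE 0.091, adjusted p = 0.371). In the ribosome biogenesis list 3 of 11 genes fell and 8 did not pass, with 7 lower when adjusted over the list alone and a median of −0.21 (camera adjusted p = 0.00046; adjusted p = 0.431 with an estimated correlation). The genes were RRP9, a U3 small nucleolar RNA-binding protein (−0.64, SE 0.11), FBL, the methyltransferase fibrillarin (−0.46, SE 0.063), and NPM1, nucleophosmin (−0.23, SE 0.065), whose adjusted p ranged from 0.0491 to 0.132 in the fits without 1 array and was 0.179 with the 18S covariate. RRP9 and FBL kept their call with that covariate. The list mean was −0.037 in cocoa array 1, −0.20 in cocoa array 2 and −0.16 in cocoa array 3, against 0.078 to 0.13 in the controls.

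In the heat shock list 6 of 10 genes fell, 1 rose and 3 did not pass (8 lower and 1 higher when adjusted over the list alone; median −0.27; camera adjusted p = 0.000192; adjusted p = 0.369 with an estimated correlation). HSPH1, a nucleotide exchange factor of HSP70 (−0.73, SE 0.078), and its relative HSPA4L (−0.71, SE 0.078) kept their call in every fit without 1 array. HSPD1, the mitochondrial chaperonin, and DNAJB1, an HSP70 co-chaperone, fell by 0.36 (SE 0.078) and 0.35 (SE 0.074). Their adjusted p ranged over 0.00721 to 0.0613 and over 0.0076 to 0.0622 without 1 array. The member that rose was HSPB1, a small heat shock protein (0.29, SE 0.075), with an adjusted p of 0.0262 to 0.138 without 1 array. Of the 7 members called, 2 kept their call with the 18S covariate and 3 with the 5′ to 3′ covariate. The list mean was −0.10 in cocoa array 1, −0.18 in cocoa array 2 and −0.21 in cocoa array 3, against 0.11 to 0.15 in the controls.

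Metallothioneins, small proteins that bind zinc and copper, were higher with cocoa. Of 10 genes of the metallothionein and zinc list 6 rose, 1 fell and 3 did not pass (7 higher and 1 lower when adjusted over the list alone; median 0.405; camera adjusted p = 2.86e-05; adjusted p = 0.221 with an estimated correlation). MT2A rose 1.78-fold (log2 difference 0.83, SE 0.063), MT1X 1.71-fold (0.77, SE 0.082), MT1F 1.58-fold (0.66, SE 0.081) and MT1H 1.44-fold (0.52, SE 0.076). The gene that fell was SLC39A10, a zinc importer (−0.42, SE 0.075), with an adjusted p of 0.0553 with the 18S covariate (0.00384 to 0.0317 in the fits without 1 array). Metallothionein transcripts are nearly identical and share probes, so the members are not independent readings. MT1E, MT1F, MT1H, MT1X and MT2A have only probe sets whose suffix marks possible matches to several transcripts, so a fit without these (5 members left, list mean 0.035, adjusted p = 0.587) does not test them.

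Of 7 histone genes with polyadenylated transcripts 3 rose and 4 did not pass, with 5 higher when adjusted over the list alone and a median of 0.30 (camera adjusted p = 0.00046; adjusted p = 0.369 with an estimated correlation). H2AC6 rose by 1.05 (SE 0.11), H2BC21 by 0.69 (SE 0.10) and H2BC12 by 0.34 (SE 0.083) on the log2 scale. The call of H2BC12 was lost without any 1 control array and without cocoa array 3 (adjusted p 0.023 to 0.0976 in the fits without 1 array). These genes also share probes with close copies, and without probe sets of the suffixes for several transcripts 4 of the 7 were left (mean 0.18, adjusted p = 0.185), H2AC6, H2BC21 and H2BC5 not among them. The goblet cell list fell in the camera test (adjusted p = 0.0229; adjusted p = 0.431 with an estimated correlation) through 3 of its 12 genes, TFF1, REG4 and SPINK4, which were also the 3 lower ones when adjusted over the list alone. Its median was −0.098 and its mean −0.46. The other 9 did not pass, among them MUC2, the main intestinal mucin (log2 difference 0.14, SE 0.087, adjusted p = 0.374). Without cocoa array 1 the adjusted p of the list was 0.0537, and over the 6 fits without 1 array it ranged from 0.00438 to 0.0537.

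The other 24 lists did not pass the camera test, and single members of most of them changed. Of 9 targets of the aryl hydrocarbon receptor, a sensor of planar aromatic compounds, 3 rose, 1 fell and 5 did not pass (the same counts when adjusted over the list alone; median −0.073, mean 0.14, adjusted p = 0.542). CYP1A1, a cytochrome P450 that oxidises such compounds, rose 2.2-fold (log2 difference 1.14, SE 0.11), and CYP1B1 rose by 0.46 (SE 0.061). AHRR, the repressor of the receptor, rose by 0.41 (SE 0.11), with an adjusted p of 0.0212 to 0.142 in the fits without 1 array. The list of NRF2 targets, genes of the oxidative stress response, had 3 higher, 5 lower and 14 not passing of 22 (5 higher and 8 lower when adjusted over the list alone; median −0.079, adjusted p = 0.422). AKR1B10, an aldo-keto reductase, fell by 0.80 (SE 0.085), PIR, a redox-responsive nuclear protein, rose by 0.66 (SE 0.072) and EPHX1, an epoxide hydrolase, rose by 0.41 (SE 0.083), with an adjusted p of 0.0867 with the 18S covariate and 0.0724 with the 5′ to 3′ covariate (0.00986 to 0.0488 in the fits without 1 array). HMOX1, the inducible heme oxygenase, fell by 0.34 (SE 0.069), with an adjusted p of 0.0645 without control array 2 and of at least 0.023 in the fits without 1 array. NQO1, a quinone reductase, had a log2 difference of 0.058 (SE 0.072, adjusted p = 0.69).

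Of 18 antioxidant enzymes 1 rose, 2 fell and 15 did not pass (1 higher and 3 lower when adjusted over the list alone; median −0.053, adjusted p = 0.286), led by GPX3, a secreted glutathione peroxidase (0.60, SE 0.079). Of 15 genes of polyphenol conjugation and efflux 1 rose, 1 fell and 13 did not pass (2 higher and 1 lower when adjusted over the list alone; median −0.022, adjusted p = 0.708). SULT1A1, a phenol sulfotransferase, had a difference of 0.44 (SE 0.067) as the mean of 3 probe sets and of −0.092 (adjusted p = 0.528) without the probe sets that can match several transcripts. ABCC1, an efflux pump, fell by 0.40 (SE 0.081), with an adjusted p of 0.0598 without control array 2 and 0.011 to 0.0598 over the fits without 1 array. In the iron list 2 of 10 genes rose and 8 did not pass (3 higher and 1 lower when adjusted over the list alone; median 0.068, adjusted p = 0.252). They were SLC40A1, the iron exporter ferroportin (0.48, SE 0.096), and CYBRD1, a ferric reductase (0.37, SE 0.094). The 2 probe sets of SLC40A1 read 0.849 (limma adjusted p over probe sets 0.000769) and 0.102 (0.823), so its rise rests on the first. The call of SLC40A1 was lost without control array 2 (adjusted p = 0.0541, the highest of a range from 0.00889), and that of CYBRD1 in 4 of the 6 fits without 1 array (0.02 to 0.101). The transferrin receptor gene TFRC had a log2 difference of −0.24 (SE 0.098, adjusted p = 0.139).

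The hypoxia list moved both ways, with 4 of 20 genes higher, 2 lower and 14 not passing (4 higher and 5 lower when adjusted over the list alone; median −0.007 and mean 0.037, camera direction downward, adjusted p = 0.906). ALDOC, an aldolase of glycolysis (0.90, SE 0.14), NDRG1, a stress-responsive gene (0.65, SE 0.10), and BNIP3L, a receptor for the removal of mitochondria (0.56, SE 0.074), rose, and EGLN3, an oxygen-sensing prolyl hydroxylase, fell by 0.46 (SE 0.089), with an adjusted p of 0.0753 and 0.0614 with the 18S and the 5′ to 3′ covariate (0.00568 to 0.0488 in the fits without 1 array). In the list of ATF4 and the amino acid response 4 of 19 fell and 15 did not pass (6 lower and 1 higher when adjusted over the list alone; median −0.13, adjusted p = 0.229). The 4 were SLC3A2, ATF3, SLC7A5 and SHMT2, and each lost its call in at least 3 of the 6 fits without 1 array. The list as a whole passed without cocoa array 3 (mean −0.28, adjusted p = 0.00014), and its adjusted p ranged from 0.00014 to 0.696 over those fits. Of 15 endoplasmic reticulum chaperones 1 rose, 2 fell and 12 did not pass (1 higher and 2 lower when adjusted over the list alone; median 0.012, adjusted p = 0.983), with DNAJB9, a co-chaperone of the unfolded protein response, 0.47 higher (SE 0.073) and MANF, a secreted stress-induced factor, at −0.35 (SE 0.065). The adjusted p of MANF was 0.0522 with the 18S covariate, and 0.0175 to 0.042 in the fits without 1 array.

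Inflammatory genes were divided. Of 18 genes of the NF-κB list 2 rose, 3 fell and 13 did not pass, with the same counts when adjusted over the list alone (median −0.066, adjusted p = 0.483). The chemokine gene CXCL10, which is also induced by interferon, rose by 0.67 (SE 0.12), whereas NFKB1, a subunit of NF-κB (−0.59, SE 0.069), and CXCL8, the neutrophil chemokine interleukin 8 (−0.49, SE 0.081), fell. PTGS2, the inducible cyclooxygenase, rose by 0.28 (SE 0.069), with an adjusted p of 0.028 to 0.113 in the fits without 1 array. Of 16 MAPK and immediate early genes 1 rose, 4 fell and 11 did not pass (1 higher and 6 lower when adjusted over the list alone; median −0.065, adjusted p = 0.229). Those that fell were FOSL1, PHLDA1 (−0.48, SE 0.067) and the MAPK phosphatases DUSP5 (−0.41, SE 0.066) and DUSP4 (−0.34, SE 0.063). Without its _s_at probe set DUSP4 had a difference of −0.246 and did not pass (adjusted p = 0.065, the highest of its alternatives, which start at 0.00552).

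Of 14 Wnt targets and crypt stem cell genes 2 rose, 2 fell and 10 did not pass, the same when adjusted over the list alone (median 0.018, adjusted p = 0.878). ZNRF3, a ubiquitin ligase that removes Wnt receptors, rose by 0.61 (SE 0.078), and LGR5, a marker of crypt stem cells, fell by 0.56 (SE 0.092). MYC, a transcription factor of growth, fell by 0.32 (SE 0.086), with an adjusted p of 0.041 to 0.142 in the fits without 1 array. Of 10 YAP targets 1 rose, 2 fell and 7 did not pass (1 higher and 4 lower when adjusted over the list alone; median −0.13, adjusted p = 0.0803). The receptor kinase gene AXL fell by 0.40 (SE 0.074). CCN2, a matricellular growth factor, fell by 0.91 (SE 0.18), with an adjusted p of 0.0509 without control array 2 and 0.002 to 0.0509 over the fits without 1 array. The YAP list passed without control array 1 (adjusted p = 0.0201) and without cocoa array 2 (adjusted p = 0.00817), within a range of 0.00817 to 0.276.

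Among 19 enterocyte genes 3 rose and 16 did not pass (3 higher when adjusted over the list alone; median 0.071, adjusted p = 0.182). They were CDH17, an intestinal cadherin (0.56, SE 0.12), DPP4, a brush border peptidase (0.39, SE 0.065), and CEACAM7, an adhesion molecule of the colon (0.34, SE 0.079). The call of CDH17 was lost without control array 2 and that of CEACAM7 without any control array or without cocoa array 2, at an adjusted p of up to 0.0555 and 0.0779. The differentiation keratin KRT20 had a log2 difference of 0.23 (SE 0.083, adjusted p = 0.105). Of 9 enteroendocrine genes only SCG5, a secretory granule chaperone, rose (0.85, SE 0.063) and 8 did not pass (1 higher when adjusted over the list alone; median 0.045, adjusted p = 0.3). In the p53 list 2 of 11 rose and 9 did not pass (2 higher when adjusted over the list alone; median 0.013, adjusted p = 0.291). CDKN1A, the cell cycle inhibitor p21, rose by 0.46 (SE 0.095) but had an adjusted p of 0.0504 without control array 3, the highest of a range from 0.00422. RRM2B, a subunit of ribonucleotide reductase, rose by 0.42 (SE 0.071).

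Lipid genes changed singly. In the list of cholesterol synthesis and uptake MSMO1, a sterol oxidase, rose (0.49, SE 0.073) and 16 of 17 did not pass (1 higher when adjusted over the list alone; median 0.036, adjusted p = 0.239). In that of fatty acid synthesis ACSS2, which makes acetyl-CoA from acetate, rose (0.79, SE 0.11), ACACA fell and 8 of 10 did not pass (1 higher and 1 lower when adjusted over the list alone, median −0.037, adjusted p = 0.897). ACACA, the first committed enzyme, was lower by 0.32 as the mean of 2 probe sets (SE 0.070, adjusted p 0.0211 to 0.071 without 1 array). These moved in opposite directions, by 0.118 (limma adjusted p over probe sets 0.487) and −0.749 (0.0117), so the fall rests on 1 of them. In the list of fatty acid oxidation and PPAR targets 2 of 12 rose and 10 did not pass (2 higher when adjusted over the list alone; median 0.055, adjusted p = 0.182). They were CPT2, a mitochondrial acyltransferase (0.39, SE 0.081), and PDK4, a kinase that inhibits pyruvate dehydrogenase (0.30, SE 0.066). Each lost its call without control array 2, at an adjusted p of 0.0637 and 0.0791, the highest of the fits without 1 array. The probe sets of PDK4 read 0.699 (limma adjusted p over probe sets 0.0115), 0.238 (0.154) and −0.032 (0.861), and only the first was called.

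Of 15 apoptosis regulators 2 fell and 13 did not pass (2 lower and 1 higher when adjusted over the list alone; median −0.023, adjusted p = 0.554), and of 24 oxidative phosphorylation genes 2 fell and 22 did not pass (0 when adjusted over the list alone; median 0.006 and mean −0.019, adjusted p = 0.827). None of these 4 calls held in more than 2 of the 6 fits without 1 array. None of 10 epithelial-mesenchymal markers passed (median 0.002, mean −0.020, adjusted p = 0.983), and none did when adjusted over the list alone. Among markers of other cell types, none of 8 fibroblast genes (median −0.035, adjusted p = 0.809) and none of 6 endothelial genes (median −0.071, adjusted p = 0.542) passed, over all genes or over the list alone. Of 7 leukocyte genes CD14, a co-receptor for bacterial lipopolysaccharide, rose (0.75, SE 0.11), and the other 6 did not pass (1 higher when adjusted over the list alone; median 0.081, adjusted p = 0.286).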

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

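The tests on leukocyte markers and on array scaling below were chosen after the results they bear on were seen, as were the covariates themselves. In the 18S ribosomal RNA control probe sets, which no comparison used, cocoa array 2 stood at 3.31 and cocoa array 3 at 1.40 (centred log2), above the highest control at 0.51. In the 28S control probe sets cocoa array 2 stood at 0.45 and cocoa array 3 at 0.26, above the highest control at 0.066. Cocoa array 1 lay below the highest control in both, at −0.51 and −0.31. The 5′ minus 3′ signal of actin and GAPDH was −0.26 in cocoa array 2 and −0.052 in cocoa array 3, against 0.032 in cocoa array 1 and 0.009 to 0.033 in the controls.

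Interferon response genes were higher with cocoa, and RNA quality, other cells or the extract are candidate explanations. With the 18S signal as a covariate the mean difference over the 16 genes was 1.44 (95% interval 1.01 to 1.87; 1.48 without it), and with the 5′ to 3′ signal 1.44 (1.03 to 1.86), which argues against either as the whole cause. Leukocyte markers had a median difference of 0.081 (SD 0.271 over 7 genes) against 1.204 for the interferon list. This argues against a share of leukocytes large enough to carry the interferon transcripts, although CD14 rose. A smaller share could not be seen this way, and whether these markers were above background is unknown. An effect of the extract on interferon signalling may account for the pattern, as a hypothesis. An interferon-inducing contaminant of the extract was not tested, and whether both groups were handled alike is not given in the sources used here.

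DNA replication genes were lower with cocoa, and RNA quality, array scaling or slower proliferation may account for it. The mean difference was −0.305 with the 18S covariate (95% interval −0.387 to −0.223; −0.366 without) and −0.31 with the 5′ to 3′ covariate (−0.381 to −0.238), so neither removed most of it. Single calls were lost more readily: 6 of 14 members stayed past the threshold with the 18S covariate and 10 with the other, in fits with fewer residual degrees of freedom. Scaling of the arrays stays open, since the median over all genes, −0.012 beside −0.354 for the list, is held near 0 by the normalisation of the deposited table. Hybridisation spike-in control probe sets were also lower in every cocoa array (−0.198 to 0.007) than in the controls (0.019 to 0.156). Poly-A spike-ins overlapped between cocoa arrays (−0.075 to 0.029) and controls (0.025 to 0.036). The signal of these spike-ins over background is unknown, so they do not settle the part of scaling. Slower proliferation and cell density at harvest stay open, as untested.

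Genes of intraflagellar transport and of the Bardet-Biedl group, both of the primary cilium, were found higher in a scan made after the data were seen. The scan took genes whose symbols share a stem as a family. Over the 26 genes the mean difference was 0.301 with the 18S covariate (95% interval 0.186 to 0.416, and 0.277 without it). With the 5′ to 3′ covariate it was 0.282 (0.151 to 0.414). These values argue against either signal as the whole cause, while RNA quality beyond these signals was not tested. Scaling of the arrays stays open here too, as the median over all genes (−0.012, beside 0.243 for these) is held near 0 by the normalisation. Spike-in control probe sets were not raised with cocoa, and those for hybridisation lay lower in every cocoa array than in any control. Those for hybridisation were at −0.198 to 0.007 (controls 0.019 to 0.156) and those for poly-A at −0.075 to 0.029 (controls 0.025 to 0.036). Their signal over background is unknown, so they do not settle it. With an estimated correlation neither family was called (camera adjusted p = 0.965 for both), in a test with little power on 6 arrays. Under either covariate 3 of 8 and 4 of 6 single calls were kept. A larger share of resting cells, which may carry a cilium, is a hypothesis that these data do not test.

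The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. In the real split 4358 probe sets, 2666 genes, 1456 higher genes, 1210 lower genes and 446 genes with at least 1.5-fold changes were called, and the highest count of any other split was 0 for each, so that 1 of the 10 splits gave as many. For gene lists the real split gave 8 calls and the highest other split 9, and 2 of the 10 splits gave as many. All other splits mixed cocoa and control arrays in both groups. For single genes this widens the spread within groups, so low counts were likely whatever the cause. For lists part of the group difference remains, so these splits do not give the count without an effect.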

How the results depend on the processing

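The covariates and the median of a gene's probe sets were added after the data were seen. All 101 named changed genes kept their sign under each alternative, except SULT1A1 at −0.092 (adjusted p = 0.528; 0.000512 to 0.528 over its alternatives) without _s_at and _x_at probe sets, where 72 were measured. Of the 101, 66 kept the call in every fit without 1 array. With the 18S and the 5′ to 3′ covariate, genes changed were 1103 and 1411, higher 787 and 919, lower 316 and 492, and probe sets 1314 and 1808, with 1 fewer residual degree of freedom. Leaving out 1 array gave 1315 (without control 2) to 2881 (without cocoa 1) genes changed, 851 to 1458 higher, 464 to 1423 lower, 1416 to 4602 probe sets, 400 to 541 genes of at least 1.5-fold and 7 to 9 lists. Lower genes fell to 719 without _s_at and _x_at probe sets, in a table of 17098 genes. At least 2-fold, 107 genes changed. Lists called were 0 with an estimated correlation and 13 with fry; beyond their construction, the cause was not tested. Over the other 14 settings, which leave out these 2 list tests, 3 values of lists fell below the threshold (metallothioneins and histones where probe sets were removed and with them called members, and goblet cell genes without cocoa 1), 9 rose past it and 436 did not change side. Same-numbered arrays did not deviate together (r −0.12, −0.0089 and −0.0031). For each number the closest partner was an array of another number, so the numbers are not taken as pairs. With the replicate block lower genes were 805, probe sets 2078 and all changed genes 1947, of which 1896 were called without it. Over all settings, 223 single values of named genes, each counted once per setting, fell below the threshold, 2 rose past it and 1333 did not change side. A robust prior gave 2639 genes, array weights 3301, quantile normalisation 2703, median centring 2665, the median of probe sets 2526 and a test against 1.2-fold 369. Quantile normalisation shifted the log2 differences by a median of 0.0015 (SD 0.0284) and median centring shifted all by 0.0075. Both changed little in a table already normalised, so their counts do not test scaling. Signal over background is unknown here, so limits by level were not assessed. The dim-probe filter and the intensity trend were not run, nor the list test under a robust prior, which camera does not offer.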

Other observations

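The gene groups below were assembled after the values were seen, and their tests describe these arrays. Genes of antigen presentation by MHC class I rose with cocoa in 9 of 14 cases, with 5 not passing and a median of 0.58 (limma camera adjusted p = 1.28e-11 over the 5 added lists; adjusted p = 0.057 with an estimated correlation). PSMB9, a subunit of the immunoproteasome, rose by 1.56 (SE 0.14) and NLRC5, a transactivator of class I genes, by 1.54 (SE 0.093). HLA-E rose by 0.98 (SE 0.10), while B2M, the light chain of class I, had a difference of 0.16 (SE 0.062, adjusted p = 0.123). HLA genes resemble each other in sequence, so their probe sets are not independent readings. Genes of RNA and DNA sensing rose in 9 of 12 cases, with a median of 0.75 (camera adjusted p = 1.28e-11; adjusted p = 0.00948 with an estimated correlation). They included IFI16, a nuclear DNA sensor (1.75, SE 0.074), RIGI, a sensor of viral RNA (1.59, SE 0.076), STING1, the adaptor of cytosolic DNA sensing (0.83, SE 0.070), and TLR3, a receptor for double-stranded RNA (0.76, SE 0.090). CGAS, the enzyme upstream of STING1, had a difference of −0.087 (SE 0.090, adjusted p = 0.611).

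Of 12 genes associated with interferon-gamma 3 rose and 9 did not pass (median 0.17; camera adjusted p = 0.00119; adjusted p = 0.0797 with an estimated correlation). HLA-DMA (0.99, SE 0.067), CXCL11 (0.94, SE 0.14) and GBP3 (0.47, SE 0.071) rose. IDO1 had −0.096 (SE 0.12), CIITA −0.016 (SE 0.080) and GBP5 −0.099 (SE 0.068), at adjusted p of 0.7, 0.935 and 0.408. Of 18 interferon ligands 1 passed, IFNL2 (0.37, SE 0.10), with an adjusted p of 0.0178 to 0.122 in the fits without 1 array; the median was −0.011 and the camera adjusted p = 0.696. IFNB1 had −0.14 (SE 0.13, adjusted p = 0.558) and IFNL1 0.035 (SE 0.074, adjusted p = 0.833). Whether these ligands were above background is unknown. Of 7 genes of polyamine synthesis and turnover 3 fell and 4 did not pass (median −0.27; camera adjusted p = 5e-05; adjusted p = 0.0561 with an estimated correlation). ODC1, the rate-limiting enzyme, fell by 0.73 (SE 0.068), SRM, spermidine synthase, fell by 0.76 (SE 0.076) and SAT1, a catabolic acetyltransferase, fell by 0.53 (SE 0.072). All 3 kept their call without each array in turn and with each covariate, while the median of the 7 was smaller in size with the 18S covariate (−0.167) and with the 5′ to 3′ covariate (−0.171).

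A scan of 319 groups of at least 8 genes whose symbols share a stem called 23 in limma's camera test, 6 higher and 17 lower. With an estimated correlation 0 were called (camera adjusted p = 0.965 for each family named here). Such groups stand in for gene families, and some, such as LINC and LOC, are only naming series. Bardet-Biedl genes rose in 6 of 8 cases (median 0.36), led by BBS12 (0.80, SE 0.075), and intraflagellar transport genes in 8 of 18 (median 0.18), led by the near-identical pair IFT70A (0.88, SE 0.13) and IFT70B (0.80, SE 0.14). Without cocoa array 2 these counts were 5 and 4, and with either covariate (18S or 5′ to 3′) 4 and 3. In every fit without 1 array 5 of the 6 and 3 of the 8 kept their call, and IFT27 and IFT88 lost theirs in each of them (adjusted p 0.0548 to 0.164 and 0.0572 to 0.156). Mitochondrial ribosomal proteins fell in 14 of 48 cases for the large subunit (median −0.21) and in 10 of 27 for the small one (median −0.23). Without cocoa array 2 the counts were 6 and 3 (medians −0.177 and −0.178), and with the 18S covariate, which costs a degree of freedom, 1 and 0 (medians −0.146 and −0.169). Of 23 nucleoporin genes 7 fell (median −0.222; 1 and −0.140 with the 18S covariate), and of 10 exosome subunits 5 fell (median −0.307; 1 and −0.234 with that covariate). The S100A family was called lower (median −0.125), with 6 of 16 genes lower, among them S100A4 (−0.89, SE 0.11) and S100A10 (−0.84, SE 0.099), and S100A14 higher (0.49, SE 0.063).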
